A study of Arabidopsis thaliana with 12 samples.

How the data were processed

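Total RNA of Arabidopsis thaliana rosette leaves was sequenced on the DNBSEQ platform, per the labels' protocols. The plants were 6 weeks old and grew under 12 h of light and 12 h of dark. The wild type was Col-0 (WT), and the mutant was jao2-1, a line affected in JASMONIC ACID OXIDASE 2 (JAO2). Leaves were left untreated or were collected 48 h after spores of the grey mould fungus Botrytis cinerea, strain B05.10, had been placed at 2 sites on each leaf. Each of the 12 libraries pooled leaves of 4 plants, with 4 leaves taken from each. The 4 groups of 3 libraries are called WT, jao2-1, WT_Bc and jao2-1_Bc. Each group was given as separate biological replicates, and RNA integrity numbers were at least 6, per the labels' protocols.

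The submitters' processing notes name FastQC 0.11.5, HISAT2 2.1.0, HTSeq, DESeq2 and the TAIR10 genome, with no role or order. The annotation used for counting, the strand setting and the treatment of reads that fit several genes are not given in the sources used here. The authors deposited 4 comparison tables, each with the 6 libraries of 2 groups. Tested on the tables, every listed gene had an adjusted p under 0.05, an absolute log2 fold change of at least 1 and a mean over both groups above 10, so genes outside these limits were not analysed here. The library columns hold a signal, the authors' normalized read count per gene, and the deposited group means and the mean over 12 libraries are in the same unit. Fold changes and their standard errors are on the log2 scale, per the file headers. The column of test statistics is a score, the ratio of the log2 fold change to its standard error, per the file headers and the deposited values. The remaining columns hold the unadjusted p-value and the adjusted p-value, per the file headers. The number of genes behind the authors' adjustment was worked out from the deposited p-values and was 22786 for WT_Bc against WT, 22275 for jao2-1_Bc against jao2-1, 18186 for jao2-1 against WT and 19208 for jao2-1_Bc against WT_Bc.

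The normalized counts of each library were whole multiples of 1 step, the value of 1 read after division by a size factor. Dividing by that step gave whole reads, within a tolerance of 0.1 read, for 100% of the values of every library. Reads over the listed genes came to between 10575163 and 12670265 per library, and the total depth of the libraries is unknown because the tables hold part of the genes. Where a group holds 3 reads or fewer for a gene, the ratio is given with an interval at a confidence level of 0.95 or as a bound against a floor of 3 reads over the group, and both cover counting error only. The 4 tables together held 6326 genes, of which 4474 had values in all 12 libraries. The same gene and library differed by at most 0.05 between tables. For 178 genes with values in 3 groups, the mean of the remaining group was worked out from the deposited mean over 12 libraries, which on the genes with all values gave the group mean within 0.0367, and such means have no SD and enter no limma test. No column of values was left unused. Gene codes were matched by locus tag to the TAIR10.1 annotation, which gave an entry for 6263 of the 6326 genes. Because that assembly is not named as the authors' build, it was used for names and for which genes are neighbours, and no coordinates are given.

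The tables hold normalized values and not raw counts. The design fixed before the data were examined named limma for that case, in place of edgeR's quasi-likelihood test for raw counts. A limma-trend model (limma 3.58.1, R 4.3.3) with 4 group means was fitted to log2(normalized count + 1) over all 12 libraries, and genes without values in a group have no result for comparisons with that group. The Benjamini-Hochberg adjusted p was taken over the genes with values in a comparison, and genes with an adjusted p under 0.05 are called changed. Fold changes are on the log2(value + 1) scale, which understates the change of genes with low counts. All genes entered through a table of differences selected by the authors on these libraries. The adjusted p-values are therefore not genome-wide, and in the inoculation comparisons nearly every gene tested had already passed the authors' test. The overlap between comparisons was taken from the authors' lists for the same reason, which was decided after the tables were seen. The difference of the inoculation responses was tested as the interaction of the same model. Values are given as mean ± SD with n = 3, and log2 fold changes with their standard error (SE).

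The genes named were set by a rule fixed before the data were examined. It takes the JAO genes, the 10 largest changes in each direction among called genes with a mean of at least 50 and no overlap between the libraries of the 2 groups, up to 4 called members of each gene list, and the 10 largest test statistics for the interaction. A table of 30 or fewer genes may be named in full. Genes named outside this rule are said to be so. The 26 lists with 328 memberships were fixed before the data were examined. They cover jasmonic acid (JA) synthesis, JA turnover, JAZ repressors, the MYC and ERF branches of the JA response, salicylic acid response, camalexin, indole and aliphatic glucosinolates, pattern-triggered immunity, ethylene, phenylpropanoids, flavonoids, detoxification, abscisic acid, photosynthesis, chlorophyll synthesis, senescence, heat shock, the clock, the cell cycle, expansins, markers of guard cells, phloem and epidermis, and reference genes. The direction of a list was tested with Fisher's exact test, two-sided, against all other called genes of the comparison, and adjusted over the 51 tests with at least 3 called members. The share of a list in the authors' tables was set against all genes the authors tested, with a one-sided Fisher's exact test adjusted over 104 tests. All members of a list were taken as tested in that step. Both Fisher's tests count genes as independent units, though all come from the same libraries, so their p-values may be too small. Set tests that need all genes, such as camera, could not be run.

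The tests were tried on simulated data before use, with 200 of 4474 genes changed by 1.5-, 2-, 4- or 8-fold. For jao2-1 against WT, limma called 14%, 54%, 86% and 98% of genes of these sizes and 5 of the 4274 unchanged genes. For jao2-1_Bc against WT_Bc the shares were 16%, 54%, 88% and 94%, with 10 unchanged genes called. For the difference of responses they were 2%, 26%, 50% and 76%, with 3 unchanged genes called. All simulated libraries had the same spread for a gene. The real median SD of log2 values was 0.148 in WT, 0.205 in jao2-1, 0.286 in WT_Bc and 0.289 in jao2-1_Bc. These shares therefore do not show how the power differs between untreated and inoculated leaves. Alternatives fixed in advance were stricter thresholds, a minimum fold change, minimum mean counts of 10 and 50, pseudocounts of 0.1 and 10, and leaving out each library in turn. The quasi-likelihood test of edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads were added after seeing the data. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Reads of the fungus were not analysed here.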

Results

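Leaf transcript levels were measured in WT and jao2-1 plants, untreated or 48 h after inoculation with the necrotrophic fungus B. cinerea, in 4 groups of 3 libraries. JAO2 belongs to a family of 2-oxoglutarate-dependent oxygenases that hydroxylate jasmonic acid, which removes the precursor of the active hormone JA-isoleucine. The design asks how the wild-type leaf responds to the fungus, and what the jao2-1 mutation changes before and after inoculation. The libraries held between 10575163 and 12670265 reads over the listed genes. Over the 4474 genes with values in all libraries, the 10 genes with the most reads took between 23.9% and 25.9% of the normalized counts in untreated libraries and between 13.1% and 16.2% in inoculated libraries.

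JAO2 (AT5G05600) was low in untreated leaves, with 174 ± 65.5 normalized counts in WT and 107 ± 10.4 in jao2-1 (SD, n = 3). The log2 fold change between these groups was -0.62 ± 0.25 (SE) and did not pass the test (limma, adjusted p = 0.143). It passed without WT replicate c (-0.98, adjusted p = 0.00409). After inoculation JAO2 reached 9547 ± 1550 in WT_Bc and 529 ± 16.5 in jao2-1_Bc, a log2 fold change of -4.16 ± 0.25 (adjusted p = 4.38e-06) and the only called decrease in inoculated mutant leaves. Inoculation raised JAO2 by 5.84 ± 0.25 on the log2 scale in WT and by 2.30 ± 0.25 in the mutant. Where the jao2-1 lesion lies in the gene is not given in the sources used here, and reads were counted over the gene as a whole. JAO3 (AT3G55970) rose on inoculation from 11.9 ± 1.77 to 5546 ± 2104 in WT and from 36.6 ± 5.53 to 4743 ± 1936 in the mutant. In untreated leaves JAO3 was higher in the mutant by 1.55 ± 0.29 on the log2 scale (adjusted p = 0.00568). JAO4 (AT2G38240) rose from 7.91 ± 5.52 to 2849 ± 1009 in WT. It had no read in the 3 untreated jao2-1 libraries, at least 7.87-fold lower than WT (adjusted p = 0.0039), and rose at least 1914-fold on inoculation there, to 1957 ± 1172. The untreated difference in JAO4 was lost with a pseudocount of 10 (adjusted p = 0.241). Neither JAO3 nor JAO4 differed between inoculated genotypes (adjusted p = 0.825 and 0.774). JAO1 was in none of the tables.

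Inoculation of WT raised the defence genes of several pathways by large factors. PR1 (AT2G14610), a marker of salicylic acid signalling, rose from 3.59 ± 0.47 to 10900.5 ± 1967 normalized counts (log2 fold change 11.20 ± 0.28, adjusted p = 3.27e-11). The plant defensin PDF1.2A (AT5G44420), a marker of the ethylene and JA pathway, rose from 42.8 ± 10 to 87431 ± 25214 (10.95 ± 0.30, adjusted p = 4.86e-11). PAD3 (AT3G26830), which makes the last step of camalexin synthesis, rose from 13.7 ± 2.12 to 30634 ± 11229, and CYP71A13 (AT2G30770), which acts earlier in that pathway, from 6.51 ± 2.01 to 19137 ± 7540. Among the genes that fell most, CER1 (AT1G02205), which makes wax alkanes, went from 17156 ± 222 to 70 ± 34.6 (-8.06 ± 0.38), the wax ester synthase WSD1 (AT5G37300) from 1395 ± 114 to 1.28 ± 0.49, and the expansin EXPA16 (AT3G55500) from 1817 ± 227 to 13.8 ± 5.69.

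In the ERF branch of the JA response, which includes the ERF regulators, the defensins, PR3 and PR4, 16 of 16 members rose (Fisher's exact test of direction, adjusted p = 0.00196). ORA59 (AT1G06160), a regulator of this branch, had 1 read over the 3 WT libraries and 3761 ± 691 normalized counts in WT_Bc, a ratio with a counting interval of 1886 to 4.15e+05. All 11 listed members of JA synthesis rose (adjusted p = 0.0148), among them AOC3 from 37.9 ± 5.14 to 3309 ± 1126 and LOX4 from 398 ± 35 to 10426 ± 3518. Of the other JA lists, 9 members of JA turnover and 9 JAZ repressors rose (adjusted p = 0.0315 for each), and the MYC branch had 12 members higher and 1 lower (adjusted p = 0.0408). The sulfotransferase gene ST2A rose from 14.8 ± 3.42 to 13621 ± 5038, and JAZ1, a repressor of the JA response, from 174 ± 10.8 to 8792 ± 773. The salicylic acid list had 16 of 20 members higher (adjusted p = 0.00196), pattern-triggered immunity 23 of 25 (adjusted p = 6.61e-05), camalexin 10 of 11 (adjusted p = 0.0223), and ethylene synthesis and perception 11 of 12 (adjusted p = 0.0148). In the last list ACS6, an enzyme of ethylene synthesis, rose from 748 ± 183 to 16246 ± 3561. Detoxification genes followed, with 15 of 17 members higher (adjusted p = 0.00196), including the transporter gene ABCG40 from 51.3 ± 5.08 to 38917 ± 15280. Of the senescence list 11 members rose (adjusted p = 0.0148), among them SAG13 from 75.9 ± 8.7 to 24362 ± 7878. The members not counted here were not in the table.

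Genes of the photosynthetic machinery fell. Of 30 members of the photosynthesis list 18 were called, all lower (adjusted p = 6.38e-06). LHCB1.3, a light-harvesting protein, fell from 661606 ± 43558 to 229950.2 ± 34058, RBCS1A, a small subunit of Rubisco, from 620810.4 ± 47604 to 224131 ± 27437, and the carbonic anhydrase CA1 from 196638 ± 7105 to 54592 ± 15361. LHCB1 and RBCS genes have near-identical copies, so the values of a single member are uncertain. All 5 called members of chlorophyll synthesis fell (adjusted p = 0.0315), with CHLH at 154221 ± 2399 before and 49810.3 ± 6850.2 after inoculation. All 5 called members of the aliphatic glucosinolate list fell (adjusted p = 0.0315), among them the regulators MYB28, from 3711 ± 42.8 to 976 ± 160.4, and MYB29. The flavonoid list had 6 members lower and 1 higher (adjusted p = 0.0447). Chalcone synthase (CHS) fell from 15786 ± 2599 to 1079 ± 450, and the regulator gene PAP2 had no read in WT and was at least 90.2-fold higher in WT_Bc. The tests of direction did not pass for the lists that follow. Abscisic acid and drought had 6 members higher and 6 lower (adjusted p = 0.581), with COR15A falling from 6382 ± 784 to 148 ± 37.5. Indole glucosinolates had 4 higher and 1 lower (adjusted p = 0.456), phenylpropanoids 4 higher (adjusted p = 0.214), heat shock and the unfolded protein response 6 higher and 1 lower (adjusted p = 0.328), the clock 1 higher and 4 lower (adjusted p = 0.237), and epidermis and trichome markers 3 lower (adjusted p = 0.113). The expansin list had 2 members lower and the guard cell list 1, the anion channel gene SLAC1, too few for the test, while no member of the cell cycle, phloem and reference lists was in the table. In the whole comparison 5504 of 5520 genes were called by limma, 3223 higher and 2281 lower. Adjusted over the list alone, each list kept its count. The authors' deposited table lists 5514 genes, 3231 higher and 2283 lower, and as these genes were selected for passing the authors' test the calls are not a separate finding.

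**Figure D1:**
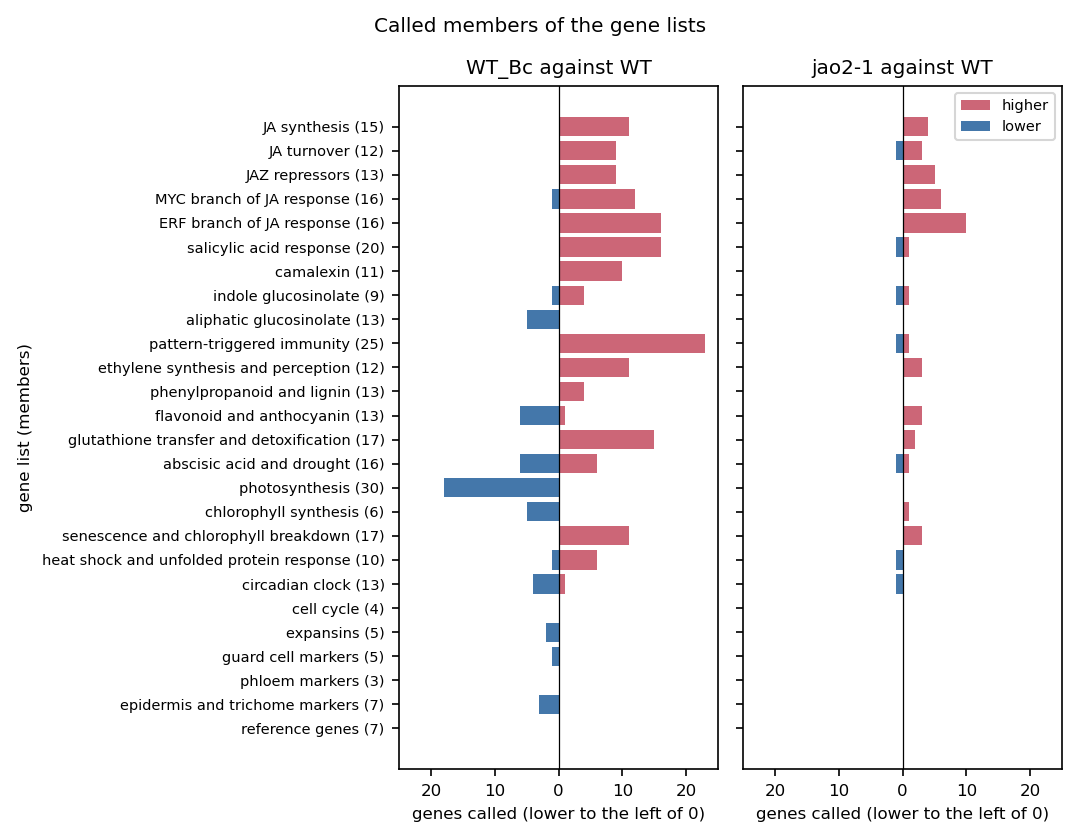
Bars show how many members of each of the 26 gene lists were called higher (right of 0) or lower (left of 0) by limma at an adjusted p under 0.05, for WT_Bc against WT (left panel) and jao2-1 against WT (right panel), with the number of list members in parentheses. The ERF branch had 16 of 16 members higher after inoculation and 10 higher in the untreated mutant, and photosynthesis had 18 members lower after inoculation and 0 called in the untreated mutant.

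The mutant leaf met the fungus with a response of similar make-up. PR1 rose from 1.35 ± 0.61 to 11509 ± 4412 normalized counts (log2 fold change 12.21 ± 0.28, adjusted p = 4.16e-11) and the berberine bridge enzyme-like gene AT1G26390, with 1 read over the untreated libraries, reached 4058 ± 1860, a ratio with a counting interval of 2145 to 4.72e+05. The peroxidase gene Prx37 (AT4G08770) rose from 2.33 ± 1.5 to 9375 ± 2830, and PAD3 from 22.4 ± 16.3 to 23030.1 ± 9931. CER1 fell from 8573 ± 1321 to 73.6 ± 41.1, WSD1 fell at least 374-fold from 347 ± 66.5 to no read, and P5CS1 (AT2G39800), an enzyme of proline synthesis, fell from 25208 ± 10024 to 599 ± 14.3. The ERF branch had 16 of 16 members higher (adjusted p = 0.00107), salicylic acid 16 (adjusted p = 0.00107), pattern-triggered immunity 22 (adjusted p = 4.2e-05), detoxification 15 (adjusted p = 0.00178), camalexin 9 (adjusted p = 0.0193) and JA turnover 8 (adjusted p = 0.0299), with none lower in these lists. Senescence had 11 higher and 1 lower (adjusted p = 0.0372). Photosynthesis had 19 members lower (adjusted p = 6.47e-06), chlorophyll synthesis 5 and aliphatic glucosinolates 5 (adjusted p = 0.0394 for each), and flavonoids 9 lower and 1 higher (adjusted p = 0.0223). JA synthesis with 6 members higher (adjusted p = 0.0629), JAZ repressors with 5 higher (adjusted p = 0.113), ethylene with 9 higher and 1 lower (adjusted p = 0.0519) and the MYC branch with 8 higher and 2 lower (adjusted p = 0.27) did not pass the test of direction. By limma 5222 of 5240 genes were called, 2869 higher and 2353 lower, and the authors' deposited table lists 5237, under the same limit as for WT.

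Without any treatment, jao2-1 leaves held raised levels of JA-responsive transcripts. PDF1.2A rose from 42.8 ± 10 normalized counts in WT to 4754 ± 1968 in jao2-1 (log2 fold change 6.70 ± 0.30, adjusted p = 4.75e-08), and the chitin-binding protein gene PR4 (AT3G04720) from 118 ± 18.7 to 2750.4 ± 838 (4.50 ± 0.21, adjusted p = 4.75e-08). PDF1.2B, PDF1.2C and PDF1.3 rose by 6.51, 5.97 and 6.50 on the log2 scale, but the coding sequences of these defensins are close enough that reads may have been shared between them. ORA59 had 1 read over the 3 WT libraries and 73.6 ± 42 normalized counts in jao2-1, a ratio with a counting interval of 36.1 to 8056. Outside the JA lists, the myrosinase-binding protein gene MBP1 (AT1G52040) rose from 328 ± 36 to 27452 ± 10359 (6.32 ± 0.23, adjusted p = 1.36e-08), its close copy MBP2 from 80.6 ± 36.6 to 2215 ± 836, and the beta-glucosidase gene BGLU18 (AT1G52400) from 4325 ± 611 to 131026 ± 48105 (4.86 ± 0.32, adjusted p = 1.04e-06).

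By list, the ERF branch had 10 of 16 members higher and 12 adjusted over the list alone. The MYC branch had 6 of 12 members with values higher, among them the acetyltransferase gene NATA1 from 37.7 ± 6.7 to 586 ± 101.6, the chlorophyllase gene CLH1 from 3538 ± 725 to 18947 ± 2064, and VSP1 from 119 ± 74.4 to 1201 ± 491. Adjusted over the list alone 7 were higher and 1 lower. Of JA synthesis, 4 of 10 members with values rose and 5 adjusted over the list alone. LOX2 (AT3G45140) rose from 24114 ± 1705 to 100244 ± 12856 (2.05 ± 0.14, adjusted p = 1.2e-05), AOS from 10609 ± 570.4 to 21954 ± 2474, and the near-identical AOC1 and AOC2 by 2.52 and 2.19 on the log2 scale. JAZ repressors had 5 of 7 members higher, also 5 adjusted over the list alone, with JAZ7 from 7.17 ± 2.38 to 102 ± 54.8 and JAZ9 from 4228 ± 306 to 13025 ± 2039. This count was 3 without WT replicate a, b or c or jao2-1 replicate b or c. Flavonoids had 3 of 10 members higher (5 higher and 1 lower adjusted over the list alone), including dihydroflavonol reductase (DFR) from 4.03 ± 2.39 to 88.2 ± 65 and the regulator PAP1 from 207 ± 23 to 535 ± 30.3. JA turnover had 3 members higher and JAO4 lower (5 higher and 2 lower adjusted over the list alone), with the amidohydrolase gene ILL6 from 282 ± 59.6 to 1219 ± 354. Senescence had 3 of 11 higher (3 adjusted over the list alone), with DIN11 from 18.4 ± 2.52 to 98.2 ± 10.6. Ethylene had 3 of 10 higher (4 adjusted over the list alone), but 1 without WT replicate a or b or jao2-1 replicate b or c, which was ACS8, from 6.79 ± 2.17 to 26.6 ± 9.94.

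The authors' deposited table lists 11 of the 16 ERF branch members for this comparison, against 2.27% of all genes tested (one-sided Fisher's exact test, adjusted p = 2.9e-13). These tests count genes as independent, and the PDF1.2 and PDF1.3 genes may share reads, so the p-values may overstate the evidence. The same test on the authors' deposited table gave adjusted p-values of 8.96e-06 for the MYC branch, 4.19e-05 for JAZ repressors, 4.19e-05 for flavonoids, 0.0012 for JA synthesis, 0.00732 for ethylene, 0.0184 for senescence and 0.0454 for indole glucosinolates. JA turnover, with 2 of 12 members listed, did not pass this test (adjusted p = 0.0738), and neither did the remaining lists. The tests of direction against other called genes did not pass for any list (lowest adjusted p = 0.066, ERF branch), where 356 of the 503 called genes were higher. Camalexin had 0 of 9 members called by limma, with 3 at an unadjusted p under 0.05 and 2 called by edgeR and by DESeq2. Photosynthesis had 0 of 17, with 1 at an unadjusted p under 0.05, 3 called by edgeR and 2 by DESeq2. Aliphatic glucosinolates had 0 of 5 called by limma, edgeR and DESeq2, with 1 at an unadjusted p under 0.05. Phenylpropanoids (0 of 4, with 0 at an unadjusted p under 0.05), expansins (0 of 2, with 1, and 1 adjusted over the list alone) and epidermis and trichome markers (0 of 3, with 1) had none called by limma and 1 each by edgeR and by DESeq2. The salicylic acid list had 2 of 15 called, GRX480 higher and PR1 lower at 3.59 ± 0.47 against 1.35 ± 0.61 (adjusted p = 0.0388). Both were lost without WT replicate a or b or jao2-1 replicate b, with adjusted p for PR1 of 0.0939, 0.0904 and 0.125. PR1 alone was lost without WT replicate c (0.11) or jao2-1 replicate a (0.101), and GRX480 alone without jao2-1 replicate c (0.0937). The GRX480 values without the first 3 libraries were 0.0928, 0.0721 and 0.0831. Pattern-triggered immunity had 2 of 22 called (2 adjusted over the list alone), with 0 without WT replicate a or b or jao2-1 replicate b and 1 without any other library. Detoxification had 2 of 15 (2 adjusted over the list alone), with 1 without WT replicate a or b and 0 without WT replicate c or jao2-1 replicate a or c. Abscisic acid had 2 of 11 (2 adjusted over the list alone), with 1 without any library except jao2-1 replicate b. Indole glucosinolates had 1 higher and 1 lower of 5 (2 higher and 1 lower adjusted over the list alone), with 1 without WT replicate a or c or jao2-1 replicate b and 0 without WT replicate b or jao2-1 replicate a or c. Chlorophyll synthesis had 1 of 5, higher (1 higher and 1 lower adjusted over the list alone), with 0 without any library except jao2-1 replicate a, and heat shock 1 of 7 (1 adjusted over the list alone), with 0 without WT replicate a or b or jao2-1 replicate b or c. The clock had 1 of 4 (2 adjusted over the list alone), which was PRR9, from 1580 ± 104 to 759 ± 153. Among lower genes, WSD1 fell from 1395 ± 114 to 347 ± 66.5, the wax gene CER4 (AT4G33790) from 413 ± 47.9 to 129 ± 30.2, and the receptor-like protein gene RLP37 (AT3G23110) from 440.1 ± 77 to 152 ± 28.

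Of 4685 genes with values, 503 were called for jao2-1 against WT, 356 higher and 147 lower, and 1136 had an unadjusted p under 0.05. The authors' deposited table lists 337 genes as higher and 75 as lower, of which 330 were also called by limma. The count was 800 by edgeR and 916 by DESeq2 on the recovered reads, both chosen after seeing the data, and 273 without WT replicate a, 272 without WT replicate b, 330 without jao2-1 replicate b and 281 without jao2-1 replicate c.

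**Figure D2:**
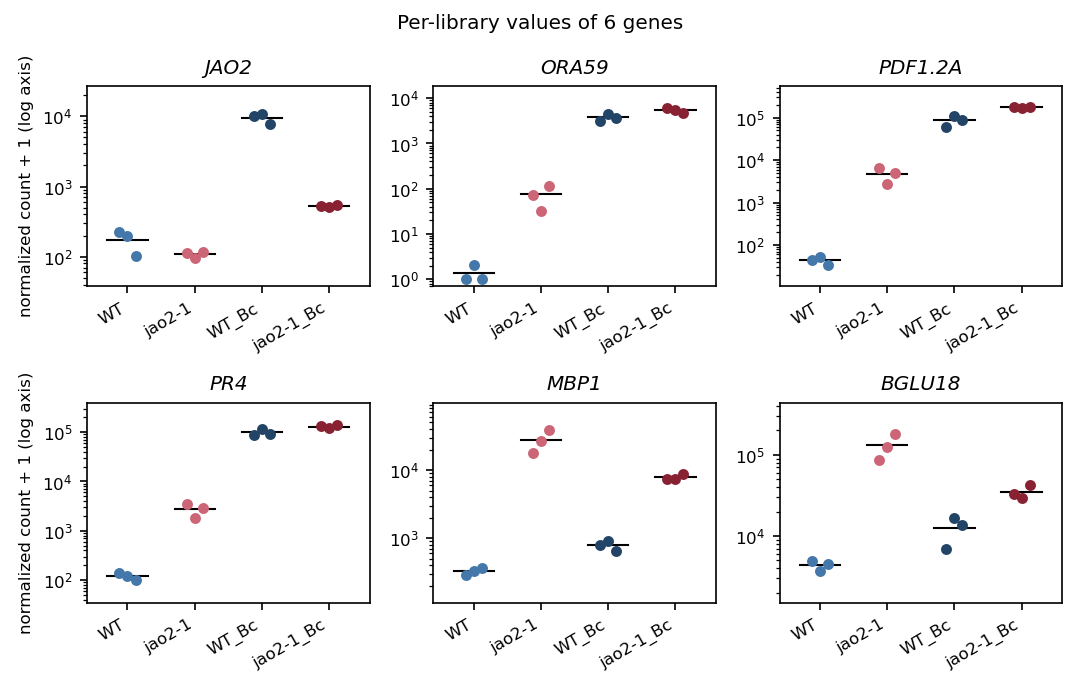
Each point is 1 library and each line the group mean of the normalized read count plus 1, on a log axis, for JAO2, ORA59, PDF1.2A, PR4, MBP1 and BGLU18 in WT, jao2-1, WT_Bc and jao2-1_Bc (n = 3). For PDF1.2A the group means are 42.8, 4754, 87431 and 176156, and for MBP1 they are 328, 27452, 787 and 7946, so that MBP1 was highest in the untreated mutant.

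After inoculation few genes differed between the genotypes, and 9 of the 13 that were higher had also been higher in the untreated mutant. The others, AT3G60170, AT3G05955, AT3G29644 and MYB17, had no values in the untreated WT libraries and were not tested there. For AT3G60170 the WT mean worked out from the mean over 12 libraries was 2.21, against 0.34 in jao2-1, so not higher there. For MYB17 these means were 8.94 and 14.42. MBP1 stood at 787 ± 138 in WT_Bc and 7946 ± 820.4 in jao2-1_Bc (log2 fold change 3.34 ± 0.23, adjusted p = 7.57e-06). AT2G16367, a gene without a description in the annotation used, stood at 65.6 ± 10 and 676 ± 45.6 (3.35 ± 0.22, adjusted p = 5.19e-06), and the jacalin-related lectin gene AT1G52000 at 3997 ± 491 and 12428 ± 1136 (1.64 ± 0.16, adjusted p = 0.000248). PDF1.3 was the 1 member of the ERF branch that passed, with 4 adjusted over the list alone, at 14940.4 ± 3881 and 65478 ± 5394 (2.16 ± 0.29, adjusted p = 0.00493), with the limit on read sharing given above. AT3G28220 stood at 1037 ± 391 and 5326 ± 852 (adjusted p = 0.00301).

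Of 4481 genes with values 14 were called, 13 higher and JAO2 lower, and 351 had an unadjusted p under 0.05. The other genes higher were AT5G35935, AT3G60170, CSLA10, MYB47, AT3G29644, MYB17, AT3G05955 and AT3G28270. The count was 8, 9 and 7 without WT_Bc replicates a, b and c and 9 without jao2-1_Bc replicate b or c, and DESeq2 on the recovered reads called 25. The authors' deposited table lists 21 genes, 16 higher and 5 lower, of which 13 were called by limma. It adds BGLU18 (log2 fold change 1.51), AT1G14250, AT1G52410 (1.11) and PAI2 (1.06) as higher, and GPAT2 (-1.23), NAS3 (-1.30), FLC (-2.58) and AT2G06995 (-3.49) as lower, values of the authors' deposited table. In both of the authors' deposited tables for the mutant 13 genes occur, all 13 with the same direction, where 0.48 would be expected of independent lists. These comparisons share no library. No member with values of the JA synthesis (0 of 6) or JAZ (0 of 5) lists was called by limma, edgeR or DESeq2, and 0 had an unadjusted p under 0.05 in either. LOX2, AOS, AOC1, AOC2, JAZ7 and JAZ9, all higher in the untreated mutant, have no jao2-1_Bc library values and were not tested. Their jao2-1_Bc means, worked out from the mean over 12 libraries, were 96794, 28588, 9466, 14002, 178 and 12980.3, against 72175, 26429, 6783, 8842, 228 and 11552 in WT_Bc. Photosynthesis had 0 of 17 called by all 3 tools, with 3 at an unadjusted p under 0.05, and the salicylic acid list 0 of 15, with 1.

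**Figure D3:**
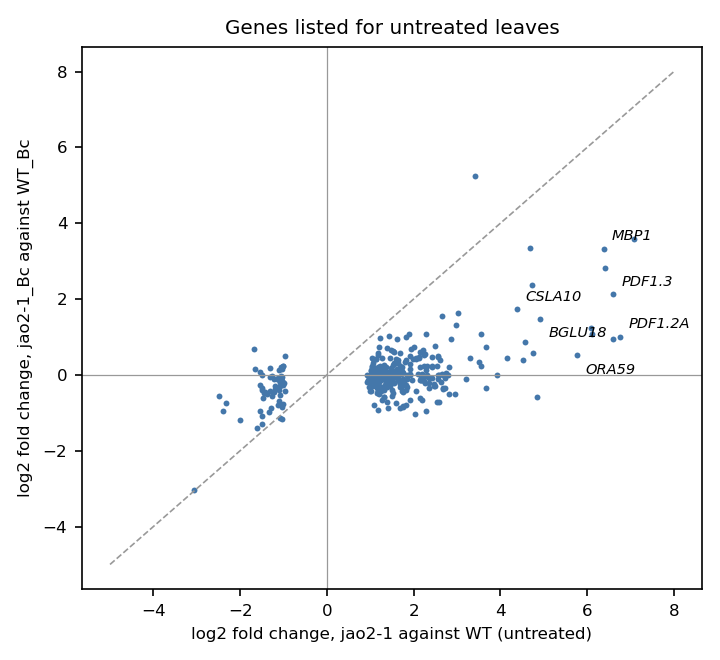
Each point is 1 of the 375 genes listed by the authors for jao2-1 against WT that have the means of all 4 groups, 174 of them with 1 mean worked out from the mean over 12 libraries, with the log2 ratio of the means of untreated leaves on the horizontal axis and that of inoculated leaves on the vertical axis, and the dashed line marks equal values. Signed by the untreated direction, the median log2 ratio was 1.55 in untreated and -0.01 in inoculated leaves for the 315 genes listed as higher, and 1.2 and 0.32 for the 60 listed as lower, and MBP1, PDF1.3 and CSLA10 lie above most other genes.

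The genes raised in the untreated mutant were largely genes that the fungus raises in WT. In the authors' deposited tables, 255 of the 337 genes higher in jao2-1 were also higher in WT_Bc against WT, where independent lists would share 59.9, and 38 of the 75 lower genes were also lower, where 9.4 would be shared. Opposite directions in the authors' deposited tables were found for 10 genes higher in the mutant and lower on inoculation (42.3 expected) and 15 genes the reverse (13.3 expected). PDF1.2A, LOX2 and JAZ6 are among the genes higher in both. Both comparisons use the WT libraries. The correlation of fold changes across 4474 genes was 0.403, against 0.511 in the simulation without effects, and the covariance was 0.77 against 0.0639. The simulated correlation comes from noise alone, so the sizes are compared by the covariance. In the simulation the shared WT libraries gave 0.0639, a small part of the observed covariance. As 3 control libraries cannot be split into parts of 2 or more, this was not checked on the real libraries. Some of the shared genes may still come from the shared controls. Against the response of the mutant, which shares the jao2-1 libraries with the opposite sign, the genes with the same direction numbered 163 in place of 293. In this setting the authors' deposited tables share 142 higher genes (53.3 expected) and 21 lower ones (9.7 expected), while 65 were higher in the mutant and lower on inoculation (43.8 expected) and 21 the reverse (11.9 expected). The correlation of fold changes was 0.253, against -0.5 in the simulation without effects.

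Across the 4474 genes with values in all libraries, the inoculation responses of the genotypes had a Pearson correlation of 0.981 and a Spearman correlation of 0.967, over genes, which are not independent replicates. The authors' deposited tables list 4467 of these genes for inoculation in both genotypes, so the correlation hardly covers genes listed for 1 genotype alone. The slope of the mutant's response on that of WT was 0.9. The same direction was seen for 4462 genes and the opposite for 12, of which 8 were called in both genotypes, among them MBP1, MBP2, BGLU18 and CSLA10. BGLU18 went from 4325 ± 611 to 12431 ± 5050.2 in WT (log2 fold change 1.44, adjusted p = 0.000752) and from 131026 ± 48105 to 34830 ± 7212 in jao2-1 (-1.86, adjusted p = 9.94e-05).

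The response differed between genotypes for 41 genes, and 39 of the 40 with a lower response were called higher in the untreated mutant. Both tests use the untreated libraries, so a higher level in untreated jao2-1 itself favours a call of a lower response. The test of the difference covered the 4474 genes with values in all libraries. The authors' deposited tables list 4467 of these for inoculation in both genotypes, so genes that responded in 1 genotype alone were hardly tested. LOX2, AOS, AOC1, AOC2, JAZ7 and JAZ9 were among the genes not tested, so the counts below are not a full tally of JA genes. PDF1.2A rose by 10.95 on the log2 scale in WT and by 5.31 in jao2-1, a difference of -5.64 ± 0.42 (interaction, adjusted p = 2.85e-05), and ended at 87431 ± 25214 and 176156 ± 5130. ORA59 ended at 3761 ± 691 and 5424 ± 670.1, with a fitted difference of -5.14 ± 0.57 that depends on the pseudocount. PR4 had a difference of -4.09 ± 0.29 (adjusted p = 2.85e-05) and ended at 99068 ± 16573 and 130157 ± 9579, NATA1 one of -3.94 ± 0.35 (adjusted p = 0.000115), and ERF2 one of -3.29 ± 0.41 (adjusted p = 0.00176). JAO2 had no called difference before inoculation and ended lower in the mutant (-3.54 ± 0.35, adjusted p = 0.000196). By list, 7 of 16 members of the ERF branch had a smaller response in the mutant, and 0 a larger one. JA turnover had 2 members, the MYC branch 2, and JAZ repressors, ethylene and senescence 1 each, all smaller in the mutant. Without jao2-1_Bc replicate c these counts were 5 for JA turnover, 4 for the MYC branch, 3 for JAZ repressors, 2 for ethylene and 3 for senescence. The turnover count was 1 without WT replicate b, jao2-1 replicate b or c, WT_Bc replicate a or b, or jao2-1_Bc replicate b, and the ethylene count was 0 without WT replicate a or b, jao2-1 replicate b or c, WT_Bc replicate a, b or c, or jao2-1_Bc replicate a or b. In salicylic acid (0 of 15), pattern-triggered immunity (0 of 22), camalexin (0 of 9) and photosynthesis (0 of 17) no member was called by limma, edgeR or DESeq2, with 3, 5, 2 and 0 at an unadjusted p under 0.05. Without jao2-1_Bc replicate c limma called 1, 2, 1 and 0 in these lists.

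Of the 41 genes called among 4474, 40 had a lower response in the mutant and 1, CER4, a higher one, as it fell by 4.15 on the log2 scale in WT and fell by 1.80 in jao2-1. An unadjusted p under 0.05 was found for 478 genes. The count was 27 without WT replicate a, 26 without WT replicate b or WT_Bc replicate b, 25 without jao2-1_Bc replicate b and 180 without jao2-1_Bc replicate c, and 99 by DESeq2 on the recovered reads. A higher response in the mutant was found for 17 of those 180 genes and 17 of the 99. By edgeR it was found for 1 of 35.

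**Figure D4:**
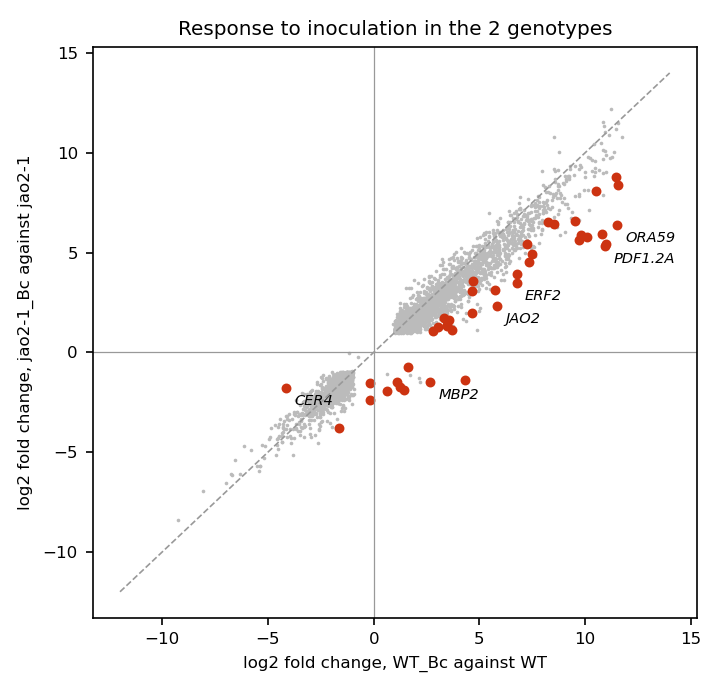
Each point is 1 of 4474 genes, with the limma log2 fold change of WT_Bc against WT on the horizontal axis and that of jao2-1_Bc against jao2-1 on the vertical axis, and the dashed line marks equal responses. The 41 genes whose responses differed at an adjusted p under 0.05 are red, and 40 of them, with PDF1.2A, ORA59, ERF2, JAO2 and MBP2 among those named, lie below the line.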

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

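The tests of the explanations below were chosen only after the result was seen, while the regrouping of the libraries was planned before. The inoculation responses of WT and jao2-1 differed, by the limma interaction test, for 41 of the 4474 genes with values in all libraries. Genes listed for inoculation in 1 genotype alone were hardly covered. The 10 genes with the largest test statistics were PDF1.2A (-5.64), PDF1.2B (-5.55), ORA59 (-5.14), PDF1.2C (-4.84), PDF1.3 (-4.33), PR4 (-4.09), NATA1 (-3.94), JAO2 (-3.54), ERF2 (-3.29) and MBP1 (-2.98), where a negative value means that the log2 fold change on inoculation was lower in jao2-1 than in WT, and MBP1 rose in WT (1.25) and fell in jao2-1 (-1.72). Reads may be shared among the PDF1.2 and PDF1.3 genes, and 24 of the 40 lower genes was the fewest kept without any 1 library.

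Of the 41 genes 40 were lower. RNA of inoculated leaves in the untreated jao2-1 libraries would put strongly raised genes at one common share of their inoculated level. The median share was 0.103% over 386 genes raised at least 32-fold in both genotypes. It was 5.62% over the 37 of the 40 genes that inoculation raised in WT. Genes raised 32-fold in jao2-1 cannot reach a share of 5.62%, so the lower median was fixed by that choice. That 386 genes rose so far still speaks against one common share of 5.62%. A less advanced infection in jao2-1 would leave these genes lower in jao2-1_Bc than in WT_Bc. Their median log2 fold change there was 0.09, against 2.68 in untreated leaves, so they were not lower as a set. Their raised level before inoculation may offset such a lag, so these genes alone cannot exclude it. Over the 4481 genes with values the median of jao2-1_Bc against WT_Bc was -0.134. That median is not signed by the inoculation response, so lags of raised and of lowered genes would offset each other in it. It does not decide the question. Reads of the fungus were not analysed, so a less advanced infection stays open. That 1 library alone made the pattern is unlikely, as at least 24 of the 40 genes stayed past the threshold without each library in turn. All 40 kept their sign, though they had been picked for large differences. Without jao2-1_Bc replicate c 180 genes were called, 163 lower and 17 higher, so whether that library hides differences stays open. Each difference of responses is the genotype difference in inoculated leaves less that in untreated leaves. Over the 40 genes the median difference of responses was -2.6, with genotype differences of 2.68 in untreated and 0.09 in inoculated leaves. As a set, the lower responses thus lay mostly in a higher level before inoculation, with 39 of the 40 called higher in untreated leaves. What raised that level was not tested, and an effect of the jao2-1 genotype stays a hypothesis. The test of the difference uses the same untreated libraries, which favours such a count. In inoculated leaves 5 were called higher, MBP1 and PDF1.3 among them, and 1, JAO2, lower.

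The number of genes that differed between genotypes fell from 503 in untreated to 14 in inoculated leaves. A larger spread between inoculated libraries alone would leave the size of the differences as it was, but over the 315 genes listed as higher in untreated jao2-1 the median log2 ratio, signed by the untreated direction, was 1.55 before and -0.01 after inoculation, while for the 60 listed as lower it was 1.2 and 0.32, which leaves this open for them. The spread was larger too, with a median SD of log2 values of 0.148 in WT, 0.205 in jao2-1, 0.286 in WT_Bc and 0.289 in jao2-1_Bc. Whether an inoculated library out of place hides genes stays open, since without jao2-1_Bc replicate c the genes at an unadjusted p under 0.05 went from 351 to 834 while the called genes numbered at most 11 without any 1 library, where each test has fewer samples. An effect of genotype that differs between untreated and inoculated leaves stays open beside it.

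Other groupings of the same libraries were tested with limma. For inoculation in WT, in jao2-1, and for jao2-1 against WT in untreated leaves, 1 of 10 ways to split the 6 libraries into 3 and 3, the real one, gave as many genes, and the highest other counts were 0, 0 and 1. With 10 ways the share cannot go under 0.05. For jao2-1_Bc against WT_Bc 3 of 10 splits gave 14 genes or more, with 217 for WT_Bc replicate a and jao2-1_Bc replicates a and b against the rest. By this count, another grouping of the inoculated libraries set apart more genes than the genotypes did. The sizes of these differences were not compared, and nearly all genes tested were ones listed for inoculation in both genotypes. For the difference of responses 10 of 100 drawn splits gave 41 genes or more, the highest 579, so by this count chance is not excluded. All 9 other such splits kept the untreated genotypes together, as 11 of the drawn ones did, and so hold the real untreated difference, and splits that mixed them gave at most 2 genes.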

How the results depend on the processing

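The alternatives were fixed before the data were seen, except edgeR and DESeq2 on the recovered reads and the lists taken from the authors, which were chosen after seeing the data. Genes changed by inoculation stayed within 1.5 times the reported counts under every alternative, at 4431 to 5512 in WT and 4185 to 5227 in jao2-1. The 503 genes for jao2-1 against WT became 232 at an adjusted p under 0.01, 66 at 0.001, 272 to 460 leaving out 1 library, 800 by edgeR and 916 by DESeq2. The 14 genes for jao2-1_Bc against WT_Bc became 7, 4, 7 to 11, 12 and 25 in the same order. The 41 genes whose responses differed became 24, 9, 25 to 180, 35 and 99. The smaller counts at stricter thresholds follow from the threshold, and for the other changes the cause was not tested. The correlation of the responses was 0.9668 by Spearman and 0.975 to 0.982 leaving out 1 library. The overlap of 293 genes was 163 with the inoculation response of jao2-1, where the shared libraries enter with the opposite sign. The tests of direction that passed numbered 24 to 26. Of 286 results for named genes 51 changed their side of the threshold under some alternative and 0 reversed. No paired analysis was possible because the library columns carry no replicate number. Not run were no filter against filterByExpr (the limma test used no such filter), Bonferroni thresholds and widened standard errors (meant for tables without library values), a replicate block, and a minimum fold change for the overlap (every listed gene already met it). Because the tables hold only genes that passed the authors' test, genes with low counts or small changes cannot be judged at this depth.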

Other observations

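The tests of gene families and of the chromosome region in this part were all chosen only after the result was seen. The family tests also count genes as independent units. In the authors' deposited table for WT_Bc against WT, 29 WRKY transcription factors were higher and 2 lower (Fisher's exact test, adjusted p = 0.000367 for direction). The authors' deposited table also had 18 calmodulin-like proteins (adjusted p = 0.00107) and 14 VQ proteins (adjusted p = 0.00352) higher and none lower. Of 31 annotated aquaporins, 14 were lower and 0 higher in the authors' deposited table (adjusted p = 8.5e-05), and of 78 annotated SAUR proteins 27 were lower and 10 higher (adjusted p = 0.00123). In the authors' deposited table for jao2-1_Bc against jao2-1 the WRKY factors numbered 28 higher and 1 lower (adjusted p = 4.82e-05) and the aquaporins 1 higher and 12 lower (adjusted p = 0.00468).

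In untreated jao2-1 leaves the authors' deposited table lists 6 of 45 jacalin-like lectins (Fisher's exact test for enrichment, adjusted p = 0.00137) and 4 of 29 xyloglucan endotransglucosylases (adjusted p = 0.00992) as higher, and 3 of 35 cysteine-rich receptor-like kinases (adjusted p = 0.00834) as lower. The thionin gene THI2.1, named after its values were seen, had no read in WT and 135 ± 114 normalized counts in jao2-1.

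MBP1, MBP2, BGLU18 and AT1G52410 lie near each other on chromosome 1. Of the 53 protein-coding genes in the stretch from AT1G51950 to AT1G52450, which was chosen around these genes, 6 (11.3%) were listed as higher in untreated jao2-1 in the authors' deposited table, against 1.85% of all genes tested. That choice favours a higher share, and 12 genes of the stretch held values for untreated leaves. Genes between MBP1 and BGLU18 are named here for their position. The log2 fold changes of jao2-1 against WT were 0 for AT1G52190, 0.05 for ROPGEF11, 0.22 for AT1G52245, 0.09 for ABA2 and 0.21 for AT1G52342. For AT1G52200 and AT1G52270 they were 1.27 and 1.37. These values argue against a rise of every neighbour. A local effect on some neighbours stays open, and no biological explanation was tested. Of 40 annotated neighbours of JAO2, the authors' deposited tables list PAI2 and PYL5 for untreated leaves and PAI2 for inoculated leaves, and whether the mutation acts on them was not tested.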
